A study of Mus musculus with 16 samples.

How the data were processed

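ATAC-seq libraries of sorted mouse melanoma cells were analysed in 4 groups read from the sample titles, B16_cas (3 libraries, replicates 1, 4 and 5), B16_SKO (5), R499_cas (3, replicates 1, 2 and 4) and R499_SKO (5). The labels' protocols refer to a published ATAC-seq protocol and give no treatment. Nothing in the labels says that the libraries came from separate animals or cultures. The p-values therefore measure only spread among these samples, pooled over peaks and groups, and that spread may be technical.

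The authors deposited 1 table of regularized log (rlog) values on the log2 scale, per the file headers and name, of Tn5 insertions in consensus peaks. Each of the 67314 peaks has an end 749 bp above its start, and whether positions count from 0 or from 1 is not stated, so coordinates are given as deposited, on mm10 per the submitters' processing notes. Those notes name cutadapt, Bowtie2, MACS2 and DESeq2 without versions or roles. How peaks were called and filtered, and whether insertions were shifted for the Tn5 overhang, is not given in the sources used here. The rlog transform adjusts for library depth and shrinks values of peaks toward their mean, so that changes of weak peaks are understated. The deposited table has 20 columns, and 4 columns match none of the samples and were not used. Which columns entered the transform is not given in the sources used here. Without counts the depth of each library is unknown.

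The genotype tag of the labels disagreed with the title in 8 libraries. The title was used for grouping, a choice made before the data were examined, and the alternatives with the tag, and with only the libraries where both agree, were run.

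Peaks were assigned with the gene spans of a RefSeq table of the assembly GRCm38.p6, which carries neither strand nor sequence. A peak went to the protein-coding gene whose span it overlaps (the nearest boundary decided among several) or otherwise to the nearest span within 50 kb. This gave 59218 peaks (88%) a gene, 15673 of 21887 genes in all, with 41488 peaks (61.6%) inside a span. Transcription start sites could not be placed without strand, and the promoter peaks that were planned became gene-end peaks, within 1 kb of either boundary (13688 peaks, 20.3%). The planned tests of sequence motifs need a genome sequence and were not run.

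Differences were tested with limma 3.58.1 in R 4.3.3 on the log2 values, with all 16 libraries in one model of the 4 groups, a variance trend, two-sided moderated tests and Benjamini-Hochberg adjustment over all peaks, at a threshold of 0.05. The comparisons were the knockout in each line, the lines with and without STAT1, and the interaction. The fit gave the prior variance 93.2 degrees of freedom, so each p rests largely on the typical spread of peaks of like level. That spread is pooled over all 4 groups. The median SD of peaks was 0.145 in B16_cas, 0.173 in B16_SKO, 0.124 in R499_cas and 0.135 in R499_SKO. The pooled spread may therefore be too small for B16 and too large for R499. Lists of genes were fixed before the data were examined, for antiviral interferon-stimulated genes, interferon-gamma GTPases and effectors, interferon signalling, MHC class I antigen presentation, T cell inhibitory ligands, melanocyte lineage, dedifferentiation, AP-1 and NF-kB, cell cycle, housekeeping genes, and markers of T and NK cells, myeloid cells, B cells, fibroblasts and endothelium. They were tested with camera (preset correlation 0.01, and an estimated one) and adjusted over the 15 lists of each comparison. The planned test fry, which does not compare a list with other peaks, was also run. Means of lists are over peaks, and genes with many peaks weigh more.

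Named genes follow a rule fixed before the data were examined. It takes, per pairwise comparison, the 8 largest increases and the 8 largest decreases among called peaks whose groups do not overlap, 1 per gene. It adds up to 3 members of each list with the smallest p, and always the peak nearest the end of Stat1, Irf1, Irf9, Ifit1, Oas1a, Isg15, Gbp2, Cd274, B2m, Tap1, Mitf and Tyr. No peak was assigned to Isg15. Other members of lists are named where they make up a count, and genes of the shared knockout decreases were named after their values were seen.

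Simulated data with 200 of 67314 peaks changed were tested first. Changes of 1 on the log2 scale were recovered at 100% of peaks in the 4 pairwise comparisons and 96.5% in the interaction. Changes of 0.5 were recovered at 61% for the knockout in B16 and 54.5% for that in R499. The shares were 36% for the lines with STAT1, 75.5% for the lines without it and 14% for the interaction. These shares hold for the simulated noise. They do not rank the lines by power in the data, where both B16 groups had a larger median SD (0.145 and 0.173) than both R499 groups (0.124 and 0.135). Of 15 simulated lists, the 1 shifted by -0.2 was called and no other.

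Alternatives were quantile normalization, subtraction of library medians, omission of peaks below the 0.25 quantile of the mean level, no variance trend, only the groups compared, library weights, the replicate number as a block, both other sources of the group, a minimum change of 0.5, a distance of 10 kb, gene-end peaks alone, an estimated correlation, and each library left out in turn. Chosen after seeing the data were regional centring, which subtracts a running median of each library's deviations along the chromosome, and class and level centring, which subtracts its median deviation within 20 bins of mean level for gene-end and other peaks. Medians and calls per chromosome were also taken after seeing the data. Tables were prepared with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.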

Results

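Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase inserts adapters into open DNA, in sorted tumour cells of the mouse melanoma lines B16 and R499. B16 is a C57BL/6 melanoma line, and R499 is a B16 derivative taken from a tumour that had relapsed after radiation with CTLA4 blockade. In each line, cells whose titles give a STAT1 knockout (SKO) were compared with the control cells of the same line (titled cas). STAT1 is the transcription factor that carries type I and type II interferon signals to the nucleus. The titles gave 3 libraries of B16_cas, 5 of B16_SKO, 3 of R499_cas and 5 of R499_SKO. Each library had a value on the log2 scale for 67314 peaks on the mm10 build. No insertion counts were used here, so the depth of each library is unknown and no interval that needs a depth is given. The library medians lay between 4.90 and 4.97, and the values of each library correlated with those of the other libraries of its group at a mean r of 0.976 to 0.989 across peaks, which are not independent replicates.

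The STAT1 locus was examined first. The peak at the gene end of Stat1 (chromosome 1, 52118983 to 52119732) read 7.6, 7.83 and 7.65 in the B16_cas libraries and 7.28, 7.58, 7.48, 7.58 and 7.4 in the B16_SKO libraries. The same peak read 7.51, 7.69 and 7.83 in R499_cas and 7.8, 7.68, 7.7, 7.69 and 7.68 in R499_SKO. The knockout differences, -0.23 in B16 (limma adjusted p = 0.40) and 0.04 in R499 (limma adjusted p = 0.95), did not pass the test. Which part of Stat1 was deleted is not given in the sources used here, and accessibility at the gene end does not check whether the gene is lost. The genotype tag of the labels disagreed with the title in 8 of the 16 libraries, whereas the deposited sample sheet gave the STAT1 status of the title in 16 of 16, and groups were therefore taken from the titles.

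The first principal component, with 25.7% of the variance, separated the lines. The B16 libraries lay between -36.5 and -18.4 on it and the R499 libraries between 15.8 and 31.3. The second component, with 9% of the variance, held B16_SKO 3 at -43.1, apart from the other B16_SKO libraries at -2.6 to 8.4. This library also had the lowest spread over peaks, with an SD of 1.253 against 1.314 to 1.339 in the other B16_SKO libraries.

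**Figure D1:**
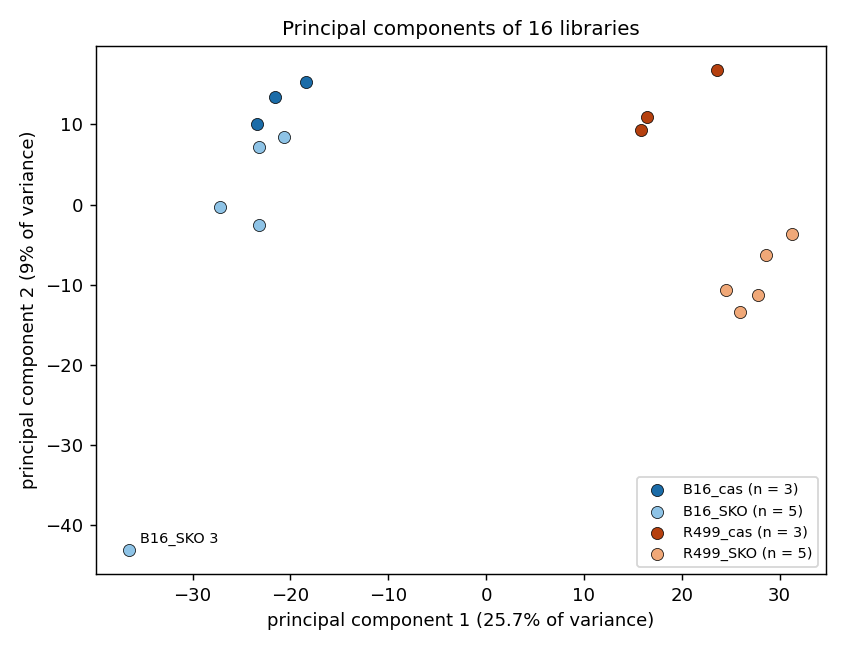
Principal components of the log2 values of all 67314 peaks, with the first component (25.7% of the variance) on the horizontal axis and the second (9%) on the vertical axis, both in component units. Each point is 1 of 16 libraries, coloured by group. The lines separate on the first component, and B16_SKO 3 lies at -43.1 on the second.

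The knockout in the parental line was examined by comparing B16_SKO with B16_cas. The SKO and cas cells of a line are separate cell populations, so differences between them may hold more than loss of STAT1. The deepest decrease was at the gene end of Trim30a (chromosome 7, 104464939 to 104465688), a member of an interferon-inducible family of tripartite motif genes, where the level was 6.52 ± 0.23 (SD, n = 3) in B16_cas and 5.14 ± 0.21 (SD, n = 5) in B16_SKO. Its log2 change was -1.38 with a standard error of 0.13 (limma adjusted p = 4.5e-13). A peak inside Oas1h (chromosome 5, 120870370 to 120871119), of the family of 2'-5' oligoadenylate synthetases that sense double-stranded RNA, fell by 1.16 (limma adjusted p = 2.2e-10), and the end of Trim12c (chromosome 7, 104353066 to 104353815) fell by 1.08 (limma adjusted p = 2.2e-10). The Trim12, Trim30 and Oas1 genes belong to families of close paralogs, so that assignment of reads among them is uncertain.

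Trim30a, Oas1h and Trim12c are in no gene list fixed before the data were examined, and further decreases of B16_SKO lay at genes of other families. The log2 change was -1.13 at a peak 12528 bp from Gm46430, -0.90 inside Slco1a6, an organic anion transporter gene, -0.90 inside Adgrb3, an adhesion receptor gene, -0.83 at the end of Pou3f2, which encodes the neural and melanocytic transcription factor BRN2, and -0.79 inside Cntn4. The largest increase was at a peak 3453 bp from Tyrp1 (chromosome 4, 80855189 to 80855938), a gene of melanin synthesis, with 6.01 ± 0.24 (SD, n = 3) in B16_cas and 7.08 ± 0.38 (SD, n = 5) in B16_SKO (log2 change 1.07, standard error 0.13, limma adjusted p = 1.8e-08). Increases of 0.71 to 0.83 followed at peaks assigned to Gpc6, Bhlhb9, Setd3, Alyref2, N4bp3, Rab40b and Fam102b, of which only the Rab40b peak lay at a gene end. The Fam102b call was lost without B16_cas 4 (limma adjusted p = 0.054) or B16_cas 5 (limma adjusted p = 0.052).

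The antiviral and sensing list, with 79 peaks at 36 genes, was lower as a group, with a mean change of -0.142 (camera adjusted p = 5.5e-09, and adjusted p = 0.0031 with an estimated correlation). Of its peaks, 59 changed below 0 and 20 above 0. Decreases passed the test at 6 peaks of 5 genes (Herc6, Ifi203, Ifit1, Usp18 and Zbp1), no peak rose, and 13 decreases passed when adjusted over the list alone. Usp18, the protease that removes ISG15 from proteins, changed by -0.71 at its gene end (limma adjusted p = 2.5e-05). Ifit1, an inhibitor of viral translation, changed by -0.66 (limma adjusted p = 0.0019, and 0.056 without B16_cas 4), and Zbp1, a sensor of Z-form nucleic acids, by -0.53 (limma adjusted p = 0.015, but 0.086 without B16_cas 4 and 0.13 without B16_cas 5). Peaks of MHC class I antigen presentation (25 peaks at 15 genes) had a mean change of -0.099 (camera adjusted p = 0.028), a call that was not made by fry (adjusted p = 0.079) and was lost with an estimated correlation (adjusted p = 0.27). It was also lost without B16_cas 1 (adjusted p = 0.21), B16_cas 5 (0.3), B16_SKO 1 (0.069) or B16_SKO 3 (0.1). In that list 1 decrease passed, at the end of the peptide transporter gene Tap1 (-0.51, limma adjusted p = 0.037), and 4 passed when adjusted over the list alone. The Tap1 call passed in 19 of the 26 alternatives that do not use the genotype tag, with values from -0.61 to -0.46. It was lost with the 2 groups fitted alone (limma adjusted p = 0.13), with library weights (0.077) and with the replicate number as a block (0.086), and without B16_cas 1, B16_cas 5, B16_SKO 2 or B16_SKO 4 (limma adjusted p = 0.17, 0.19, 0.082 and 0.085).

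No other list passed in B16. The list of interferon-gamma GTPases and effectors had a mean change of -0.053 (camera adjusted p = 0.26) and that of interferon signalling genes -0.043 (camera adjusted p = 0.23). The melanocyte lineage list had 4 peaks higher and 1 lower of 174, with a mean of -0.023 (camera adjusted p = 0.42). The lists of T cell inhibitory ligands (mean 0.002), AP-1 and NF-kB (0.003), cell cycle (-0.014), dedifferentiation (0) and housekeeping genes (-0.015) had camera adjusted p between 0.76 and 1. Markers of other cell types also did not pass, with means of 0.017 for T and NK cells, 0.04 for myeloid cells, 0.033 for B cells, 0.002 for fibroblasts and -0.049 for endothelium. Single peaks of Gbp5, Dct, Mitf, Ccnd2 and Ywhaz passed with limma adjusted p between 0.023 and 0.043, and without B16_cas 4 none of these 5 did (0.26, 0.15, 0.17, 0.086 and 0.27). The gene ends of Cd274 (-0.25), B2m (-0.10), Irf1 (-0.17), Irf9 (-0.32), Gbp2 (-0.04), Oas1a (-0.34), Mitf (-0.11) and Tyr (-0.23) did not pass.

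Whole chromosomes were shifted in this comparison. On chromosome 6 the median change was -0.075, and its 4878 peaks, 7.2% of all, held 72 of the 282 calls (25.5%), 3 higher and 69 lower, of which regional centring left 6 higher and 16 lower calls there. Its median deviation from the mean of all libraries was 0.049 to 0.06 in the B16_cas libraries and -0.046 to -0.026 in the B16_SKO libraries other than B16_SKO 3, which had 0.036. At the Trim30a end B16_SKO 3 read 5.16, within the other B16_SKO libraries (4.96 to 5.49). The shift of chromosome 6 thus did not follow STAT1 status in every library. On chromosome 8 the median was -0.073, with 0 higher and 26 lower calls by limma, and 4 higher and 11 lower after regional centring. Chromosome 12 was shifted the other way. Its median was 0.066, with 13 higher and 6 lower calls, and 4 higher and 7 lower after regional centring. Of the named peaks on chromosome 6, Slco1a6 (-0.78), Cntn4 (-0.70) and Usp18 (-0.59) still passed after regional centring and Ccnd2 (-0.39, limma adjusted p = 0.14) did not.

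By limma, 282 peaks passed in B16, 82 higher and 200 lower in the knockout. The 2 groups' libraries did not overlap at 89% of the higher and 87.5% of the lower calls, which were chosen for their small p. Over all peaks they did not overlap at 2.43% and 2.84%, where chance gives 1.79% in each direction. The total was 92 without B16_cas 4, 132 without B16_cas 5 and 451 without B16_SKO 3. It was 92 with the 2 groups fitted alone, 185 with library weights, 184 without the variance trend and 158 after regional centring (52 higher and 106 lower). Gene ends were 9.8% of the higher and 33.5% of the lower calls, against 20.3% of all peaks. After class and level centring they were 26.9% in each direction, with 130 higher and 227 lower calls. Quantile normalization gave 152 and 260. Without B16_SKO 3, which had the lowest mean excess of gene-end over other peaks (1.37), the shares were 22.6% and 33.8%. The gene-end shares and the balance of directions thus depended partly on scaling and on that library.

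The same comparison in the resistant derivative set R499_SKO against R499_cas. The deepest decrease was again at the Trim30a end, which had 6.83 ± 0.16 (SD, n = 3) in R499_cas and 4.9 ± 0.22 (SD, n = 5) in R499_SKO, with a log2 change of -1.93 (standard error 0.13, limma adjusted p = 4.2e-22). Trim12c changed by -1.21 (limma adjusted p = 6.2e-13), Oas1h by -1.06 (5.1e-09) and Ifi47, an interferon-inducible GTPase gene, by -1.09 (2.1e-09). Further decreases lay 1238 bp from Rph3a, a neighbour of the Oas genes (-1.05), 29527 bp from Clec2d (-1.01), at a peak with no gene within 50 kb (chromosome 6, 76546219 to 76546968, -0.96) and at the end of Trim30d (-0.95).

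The increases in R499_SKO were of other genes. A peak inside Nr3c2 (chromosome 8, 76901725 to 76902474), the mineralocorticoid receptor gene, had 5.06 ± 0.21 (SD, n = 3) in R499_cas and 6.06 ± 0.12 (SD, n = 5) in R499_SKO (log2 change 0.99, standard error 0.13, limma adjusted p = 5.8e-08). Ptx3, a gene of a soluble pattern recognition protein, changed by 0.94, Spef2 by 0.92, another peak inside Adgrb3 (chromosome 1, 25821949 to 25822698) by 0.82, Klhl29 by 0.82 and Lypd6 by 0.79. A peak with no gene within 50 kb (chromosome 1, 112141255 to 112142004) changed by 0.78. A peak 2859 bp outside Pdcd1, the gene of the inhibitory receptor PD-1, had 5.53 ± 0.33 (SD, n = 3) in R499_cas and 6.29 ± 0.14 (SD, n = 5) in R499_SKO (limma adjusted p = 1e-04).

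The antiviral list was lower as a group in R499, with a mean change of -0.206 (camera adjusted p = 4e-18, and adjusted p = 0.00011 with an estimated correlation). Decreases passed at 11 peaks of 11 genes (Ifi203, Ifi204, Ifit1, Ifit3b, Oas1a, Oas1g, Rsad2, Rtp4, Trim25, Usp18 and Zbp1), none rose, and 26 decreases passed when adjusted over the list alone. A peak 9773 bp from Rtp4 changed by -0.92 (limma adjusted p = 8.2e-07), the ends of Oas1a and Ifi203 each by -0.67 (3.2e-05 and 1.9e-05), and the end of Ifit1 by -0.63 (0.0021). The list of interferon-gamma GTPases and effectors had a mean change of -0.142 (camera adjusted p = 2.9e-06, and adjusted p = 0.027 with an estimated correlation). In it 2 of 43 peaks passed and 6 did when adjusted over the list alone, with Tgtp1 at -0.78 (limma adjusted p = 2.2e-05).

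MHC class I antigen presentation had a mean change of -0.216 (camera adjusted p = 1.4e-09, and adjusted p = 0.0038 with an estimated correlation). In this list 5 of 25 peaks passed, at H2-T23, Psmb9, Tap1 and Tap2, and 6 did when adjusted over the list alone. Tap2, the second subunit of the peptide transporter, changed by -0.76 at a peak 2172 bp outside the gene (limma adjusted p = 5e-06), Psmb9, an immunoproteasome subunit, by -0.52 (0.013) and Tap1 by -0.53 (0.017, but 0.065 after regional centring). All 358 peaks of chromosome 17 between 30 and 40 Mb, the interval that holds Tap1, Tap2 and Psmb9, had a median change of -0.069. Single peaks of Il18bp, Ccl5, Irgm2, Kit and Met also passed. Without R499_cas 1, the calls of Psmb9 (limma adjusted p = 0.052), Tap1 (0.075), Irgm2 (0.22), Il18bp (0.19), Ccl5 (0.074), Kit (0.13) and Met (0.22) were lost, and those of Psmb9 (0.21), Tap1 (0.13), Irgm2 (0.22), Il18bp (0.16), Ccl5 (0.19) and Met (0.18) were lost without R499_cas 4. Tap1 and Met were lost without R499_cas 2 too (0.096 and 0.15), and without R499_SKO 1 (0.065 and 0.12) or R499_SKO 3 (0.067 and 0.079). Psmb9 also missed the threshold without R499_SKO 3 (0.066), and Met without R499_SKO 2, 4 or 5 (0.12, 0.054 and 0.075).

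Interferon signalling genes had a mean change of -0.025 (camera adjusted p = 0.49) and T cell inhibitory ligands -0.043 (camera adjusted p = 0.29). Melanocyte lineage (-0.036), housekeeping (-0.038), AP-1 and NF-kB (-0.011), cell cycle (0.002) and dedifferentiation (0.007) had camera adjusted p between 0.21 and 0.89. The melanocyte list passed after regional centring (-0.047, adjusted p = 0.038) and without R499_cas 4 (-0.051, 0.045), and turned to 0.071 with gene-end peaks alone. With those peaks alone, the lists of T cell inhibitory ligands (-0.107, adjusted p = 0.048) and housekeeping genes (-0.102, 0.0075) passed too. These restricted lists were still tested against all peaks rather than against other gene ends. Markers of T and NK cells (0.003), myeloid cells (0.018), B cells (0.003), fibroblasts (0.01) and endothelium (-0.004) had a camera adjusted p of 0.89 each. The gene ends of Cd274 (0.02), B2m (-0.10), Irf1 (-0.26), Gbp2 (-0.14), Mitf (0.11) and Tyr (0.02) did not pass. The end of Irf9, a partner of STAT1 in the type I interferon response, changed by -0.43 (limma adjusted p = 0.082), and passed with the 2 groups fitted alone (0.011) or with library weights (0.024).

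In R499, 448 peaks passed by limma, 196 higher and 252 lower in the knockout, without overlap of the groups at 95.4% and 91.7% of these selected peaks, and at 4.55% and 4.19% of all peaks (1.79% by chance in each direction). The total was 156 without R499_cas 1, 253 without R499_cas 2, 231 without R499_cas 4, 289 without R499_SKO 2 and 274 without R499_SKO 3. It was 1397 with the 2 groups fitted alone and 1563 with library weights. Regional centring gave 377 calls (155 higher and 222 lower), with 338 of the 448 kept. Medians of chromosomes were shifted in R499 as well. Chromosome 15 (median 0.069) held 24 higher and 4 lower calls, and 10 and 6 after regional centring. Chromosome 3 (0.042) held 24 and 9, and 16 and 12 after it. Chromosome 17 (-0.037) held 4 and 27, and 4 and 17 after it. Chromosome 11 (-0.032) held 2 and 16, and 2 and 12 after it.

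**Figure D2:**
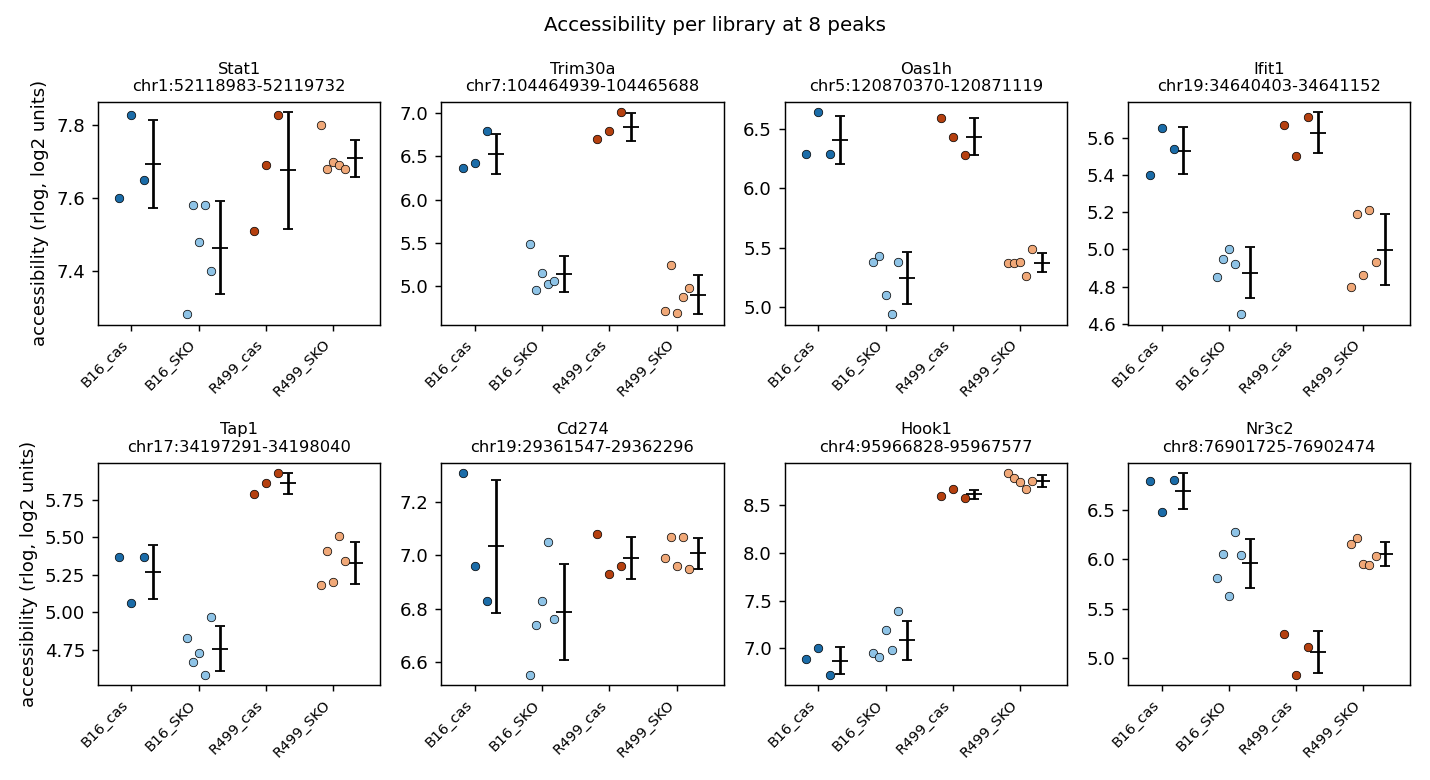
Log2 value (vertical axis) of 8 peaks, at Stat1, Trim30a, Oas1h, Ifit1, Tap1, Cd274, Hook1 and Nr3c2, in the 4 groups. Points are libraries and bars are the mean ± SD (n = 3 or 5). Trim30a fell from 6.52 to 5.14 in B16 and from 6.83 to 4.9 in R499, and Hook1 differed between the lines with and without STAT1.

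The knockout changes of the lines share no library, which allows a direct comparison. Peaks lower in both lines numbered 19, where independent lists would share 0.749, and those higher in both numbered 2, where 0.239 would be shared. Another 3 were lower in B16_SKO and higher in R499_SKO (0.582 from independent lists), and 0 were higher in B16_SKO and lower in R499_SKO (0.307). Among the 19 were the peaks of Trim30a, Trim12c, Oas1h, Rph3a, Clec2d, Usp18, Zbp1, Ifi203, Ifit1 and Tap1 named above. The others, chosen after their values were seen, were assigned to Ifi211 and Trim34a, both of interferon-inducible families, a second site each in Trim30a and Clec2d, and Isyna1, Fam13a, Vmn2r85 and Syne3, with 1 peak near no gene. Of the 252 peaks lower in R499_SKO, 71% changed below 0 in B16 (median -0.12), and of the 200 lower in B16_SKO, 59.5% changed below 0 in R499 (median -0.05). Of the 82 higher in B16_SKO, 65.9% were above 0 in R499, and of the 196 higher in R499_SKO, 55.1% were above 0 in B16 (median 0.03 each). Over all peaks, 50% lay on either side of 0 in R499, and in B16 50.3% lay above and 49.7% below. Over all peaks the correlation of the knockout changes between the lines was 0.06.

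Whether the knockout acted differently in the lines was tested by the interaction, the change in R499 minus the change in B16. The Nr3c2 peak changed by -0.73 in B16 and 0.99 in R499, a difference of 1.72 (limma adjusted p = 8.4e-11). Spef2 differed by 1.17, a peak inside Adgrb3 (chromosome 1, 25430347 to 25431096) by 1.11, Nkain3 by 0.91 and Slco1a6 by 0.73. The knockout change was lower in R499 at Tyrp1 (-1.13), Bhlhb9 (-1.04), Alyref2 (-0.94), Rab40b (-0.84) and Fam102b (-0.84). At the interferon lists the difference did not pass, with means of -0.064 for antiviral genes (camera adjusted p = 0.25), -0.089 for interferon-gamma GTPases (0.16), -0.117 for MHC class I (0.16) and 0.018 for interferon signalling (0.81). Without R499_cas 2 the antiviral (0.023), interferon-gamma (0.0081) and MHC class I (0.016) lists passed, and without B16_cas 5 the interferon-gamma and MHC class I lists did (0.042 each).

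The remaining lists had interaction means between -0.046 and 0.045, with camera adjusted p of 0.81 or 0.93. By limma, 166 peaks passed, 105 higher and 61 lower, and regional centring gave 51 higher and 48 lower. Chromosome 6, with a median interaction of 0.095, held 30 of the higher and 1 of the lower calls, and chromosome 8, with a median of 0.064, held 15 and 2. After regional centring they held 6 higher and 7 lower, and 6 higher and 3 lower. The total was 74 without B16_cas 4, 109 without B16_cas 5, 324 without B16_SKO 3, 66 without R499_cas 1, 83 without R499_cas 2, 99 without R499_SKO 1 and 94 without R499_SKO 3. It was 106 without the variance trend and 349 with library weights.

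How the resistant line differed from its parent with STAT1 present was asked by comparing R499_cas with B16_cas. The end of Hook1 (chromosome 4, 95966828 to 95967577), an adaptor of microtubule transport, had 8.62 ± 0.05 (SD, n = 3) in R499_cas and 6.87 ± 0.15 (SD, n = 3) in B16_cas, a log2 change of 1.74 (standard error 0.11, limma adjusted p = 1.7e-23). The end of Car2, a carbonic anhydrase gene, changed by 1.69 and that of Phyhipl by 1.58. Increases of 1.35 to 1.52 lay 4229 bp from Ywhag and at the ends of Eda, an ectodermal signalling ligand, A830018L16Rik, Pm20d2 and Nexmif. The peak inside Nr3c2 was lower in R499, with 5.06 ± 0.21 against 6.69 ± 0.18 (SD, n = 3 each; log2 change -1.63, standard error 0.14, limma adjusted p = 1.7e-15).

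Other decreases in R499_cas were -1.41 at a peak with no gene within 50 kb (chromosome 8, 116142758 to 116143507), -1.37 at a peak 30057 bp from the semaphorin receptor gene Plxna2, -1.27 inside Ctnnd2, -1.22 inside Tafa5, -1.21 near Gm46430, -1.21 inside the transcription factor gene Foxp1 and -1.18 inside Pard3b. All of the 8 named increases except that near Ywhag lay at gene ends, and none of the 8 named decreases did. Over all calls, 57.7% of the higher and 4.1% of the lower peaks lay at gene ends, against 20.3% of all peaks. On every R499 library gene-end peaks exceeded other peaks by a mean of at least 1.63, and on every B16 library by at most 1.52.

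MHC class I antigen presentation was higher in R499_cas by a mean of 0.219 (camera adjusted p = 1.8e-05, but adjusted p = 0.056 with an estimated correlation). Of its 25 peaks 3 rose, none fell, and 5 rose when adjusted over the list alone. The end of Tap1 changed by 0.59 (limma adjusted p = 0.0059), that of H2-Q4 by 0.58 (0.0064) and that of Psmb9 by 0.46 (0.033). After regional centring the values were 0.45, 0.42 and 0.32 and no longer passed (limma adjusted p = 0.06, 0.081 and 0.19), whereas the list still passed with a mean of 0.129 (camera adjusted p = 0.027). The median change of chromosome 17 between 30 and 40 Mb was 0.116. Tap1 also missed the threshold without B16_cas 4 (0.069), and H2-Q4 without B16_cas 5 (0.068) or R499_cas 1 (0.094). Psmb9 missed it without any 1 of the 6 libraries of the comparison (0.052 to 0.22).

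The AP-1 and NF-kB list was higher by a mean of 0.082 (camera adjusted p = 0.0095, but adjusted p = 0.11 with an estimated correlation). Of 116 peaks 8 rose and 2 fell, and 9 and 2 did when adjusted over the list alone. The end of Batf, an AP-1 family member, changed by 0.70 (limma adjusted p = 0.00064), that of Nfkbia, the NF-kB inhibitor, by 0.58 (0.00029), and a peak 14680 bp from the chemokine gene Cxcl1 by -0.73 (7e-04). The list's call was lost without R499_cas 4 (camera adjusted p = 0.11), after regional centring (0.13) and after class and level centring (0.055). The antiviral list did not pass (mean 0.05, camera adjusted p = 0.30), with 2 of 79 peaks higher, at the ends of Trim25 (0.80, limma adjusted p = 7.7e-05) and Parp12 (0.77, 4.8e-05). It passed without R499_cas 2 (camera adjusted p = 0.039). The list of interferon-gamma GTPases had a mean of 0.075 (0.15), with 3 peaks higher and 1 lower, and passed without R499_cas 2 (0.0081). That of interferon signalling had a mean of 0.038 (0.30), with 2 higher, at Jak2 and Sp110, and 2 lower, at Jak1 and inside Stat1 (chromosome 1, 52149801 to 52150550, -0.55, limma adjusted p = 0.0078, but 0.064 without B16_cas 1 and 0.054 without R499_cas 2). Restricted to peaks within 10 kb of a gene, the interferon-gamma (0.102, camera adjusted p = 0.041) and interferon signalling (0.07, 0.041) lists passed. With gene-end peaks alone their means were 0.152 (0.015) and 0.236 (1.2e-05). Both restrictions were tested against all peaks, and all gene-end peaks had a median change of 0.113 here, against -0.031 for other peaks. Passes under these restrictions, for any list of this comparison, therefore do not separate the list from gene ends as a class.

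Melanocyte lineage genes had 7 peaks higher and 3 lower of 174, and the list did not pass (mean 0.027, camera adjusted p = 0.34). A peak inside Mitf, the master regulator of the lineage, changed by 0.45 (limma adjusted p = 0.0031) and a peak inside Trpm1 by 0.58 (0.0024). The 3 lower peaks were another of Mitf, 1 of Gpnmb and 1 inside Dct (-0.60, limma adjusted p = 0.0035, but 0.056 without R499_cas 4), a gene of melanin synthesis that also had a higher peak. After regional centring the list passed (0.065, camera adjusted p = 0.03). Housekeeping genes had a mean of 0.068 (camera adjusted p = 0.15) and passed without B16_cas 1 (0.034) or R499_cas 2 (0.038), within 10 kb (0.0098) and with gene-end peaks alone (0.019). Dedifferentiation (-0.018), cell cycle (0.035) and T cell inhibitory ligands (-0.009) did not pass, although the cell cycle list did within 10 kb (0.071, camera adjusted p = 0.049) and with gene-end peaks alone (0.105, 0.024). Neither did markers of T and NK cells (0.001), myeloid cells (-0.055), B cells (0.01), fibroblasts (-0.035) and endothelium (-0.054). In the myeloid list a peak 8188 bp from Fcgr3 changed by -0.82 (limma adjusted p = 5.2e-05), whereas another peak of Fcgr3 and the end of Cd14 were higher. The Cd14 end changed by 0.47 (limma adjusted p = 0.012), but not without B16_cas 1 (0.068), R499_cas 1 (0.071) or R499_cas 4 (0.065), nor after regional centring (0.062).

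By limma, 2689 peaks passed, 1310 higher and 1379 lower in R499_cas, and subtracting each library's median gave 1954 higher and 977 lower, whereas quantile normalization gave 715 and 1027, class and level centring 689 and 1024, and a change of at least 0.5 gave 507 and 808. Which direction had more calls thus depended on the scaling. The groups did not overlap at 95.2% and 95.4% of the calls and at 10.9% and 11.1% of all peaks, where chance gives 5% in each direction. The total was 1662 without B16_cas 5, 1429 without R499_cas 1, 1609 without R499_cas 2 and 1161 without R499_cas 4. It was 1742 after quantile normalization, 1657 after regional centring and 1713 after class and level centring. Medians of chromosomes were shifted here too. Chromosome 15 (median -0.081) held 18 higher and 146 lower calls, and chromosome 6 (-0.071) held 38 and 233. After regional centring these were 35 and 41, and 81 and 78. Between the knockout cells the medians were -0.02 and 0.004, so neither shift of that size was found without STAT1. The median deviation of chromosome 15 was -0.072 to -0.052 in R499_cas and 0.002 to 0.041 in all other libraries. That of chromosome 6 was 0.049 to 0.06 in B16_cas and -0.046 to 0.036 in all others. Each shift thus set 1 group apart rather than the lines. Chromosome 10 lay higher (0.059), with 187 higher and 32 lower calls, and 62 and 44 after regional centring. It was not shifted as a whole. Windows along it had medians from -0.039 to 0.053 up to position 60000000 and from 0.051 to 0.136 beyond.

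The lines were also compared without STAT1, in R499_SKO and B16_SKO. The end of Hook1 was again higher in R499, with 8.76 ± 0.06 against 7.08 ± 0.2 (SD, n = 5 each; log2 change 1.67, standard error 0.09, limma adjusted p = 1.2e-30). Ywhag (1.66), Phyhipl (1.53), Eda (1.5), the thyroid hormone transporter gene Slc16a2 (1.45), Nkain3 (1.44), Pdcd1 (1.37) and B3gat2 (1.32) followed. The peak near Pdcd1 had 6.29 ± 0.14 in R499_SKO and 4.92 ± 0.19 in B16_SKO (SD, n = 5 each). The deepest decreases lay at peaks with no gene within 50 kb, with -1.73 on chromosome 7 (70266893 to 70267642) and -1.5 on chromosome 4 (88941741 to 88942490). Further decreases were -1.47 at a peak 26543 bp from Setd3, -1.46 near Plxna2 and -1.19 near N4bp3.

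By camera no list passed as a group without STAT1, although single members did, in both directions in most lists. By fry, interferon signalling (adjusted p = 0.0057), AP-1 and NF-kB (0.0065) and MHC class I (0.021) passed as higher. T cell inhibitory ligands passed as lower by fry (adjusted p = 0.012). Within 10 kb of a gene, the lists of interferon signalling (0.09, camera adjusted p = 0.017), AP-1 and NF-kB (0.103, 0.011) and cell cycle (0.104, 0.011) passed. With gene-end peaks alone, these 3 (0.238, 0.191 and 0.178, camera adjusted p = 1.7e-05, 1.7e-05 and 2e-04), MHC class I (0.193, 0.0015), melanocyte lineage (0.114, 0.019) and dedifferentiation (0.103, 0.035) did. Both restrictions were tested against all peaks, not against other peaks of their kind. Gene ends as a class were raised in R499, so these passes do not single out the lists. Of the melanocyte lineage peaks 20 were higher and 20 lower (mean 0.014, camera adjusted p = 0.87). A peak inside Mitf changed by 0.78 (limma adjusted p = 2.9e-13) and a peak inside Pmel, a gene of the melanosome matrix, by 0.90 (1.3e-10). Interferon signalling genes had 13 peaks higher and 6 lower of 92 (mean 0.057, camera adjusted p = 0.20), MHC class I had 4 higher and none lower (mean 0.102, 0.20), and AP-1 and NF-kB had 18 higher and 5 lower (mean 0.068, 0.17). Antiviral genes had 7 peaks higher and 5 lower (mean -0.014, 0.87) and interferon-gamma GTPases 2 higher and 3 lower (mean -0.015, 0.87). At the end of Tap1 the change was 0.57 (limma adjusted p = 5.3e-05) and at that of Gbp5, a guanylate-binding protein gene, 0.70 (9.7e-07). T cell inhibitory ligands had 6 peaks higher and 9 lower (mean -0.055, camera adjusted p = 0.38), and the end of Cd274 did not pass.

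Dedifferentiation genes had 8 peaks higher and 9 lower (mean -0.01, camera adjusted p = 0.87), cell cycle genes 10 and 4 (mean 0.051, 0.27) and housekeeping genes 3 and 0 (mean 0.046, 0.38). Markers of T and NK cells (-0.014), myeloid cells (-0.077), B cells (-0.021), fibroblasts (-0.027) and endothelium (-0.009) had camera adjusted p between 0.27 and 0.87. The peak inside Stat1 was lower in R499_SKO (-0.47, limma adjusted p = 0.00056). The Stat1 end changed by 0.25 (limma adjusted p = 0.046). The call at the end passed in 13 of the 26 alternatives without the genotype tag, with values from 0.04 to 0.33. It missed the threshold after quantile normalization (0.08, adjusted p = 0.62) and class and level centring (0.04, 0.81), without the variance trend (0.077), with the 2 groups fitted alone (0.051) and with a change of at least 0.5. It also missed it without B16_SKO 1 (0.14), B16_SKO 5 (0.083), R499_cas 2 (0.055) or R499_SKO 1, 2, 3, 4 or 5 (0.12, 0.066, 0.075, 0.073 and 0.065).

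By limma, 11779 peaks passed without STAT1, 6174 higher and 5605 lower in R499_SKO, and subtracting each library's median gave 8479 and 3905, whereas quantile normalization gave 4030 and 4216 and class and level centring 3743 and 4145. The groups did not overlap at 57.9% of the higher and 45.7% of the lower calls and at 6.1% and 4.46% of all peaks, where chance gives 0.397% in each direction. Gene-end peaks made up 55.7% of the higher and 4% of the lower calls. The larger count than with STAT1 goes with larger groups, 5 libraries against 3, and the counts of the 2 comparisons do not test a difference between them.

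**Figure D3:**
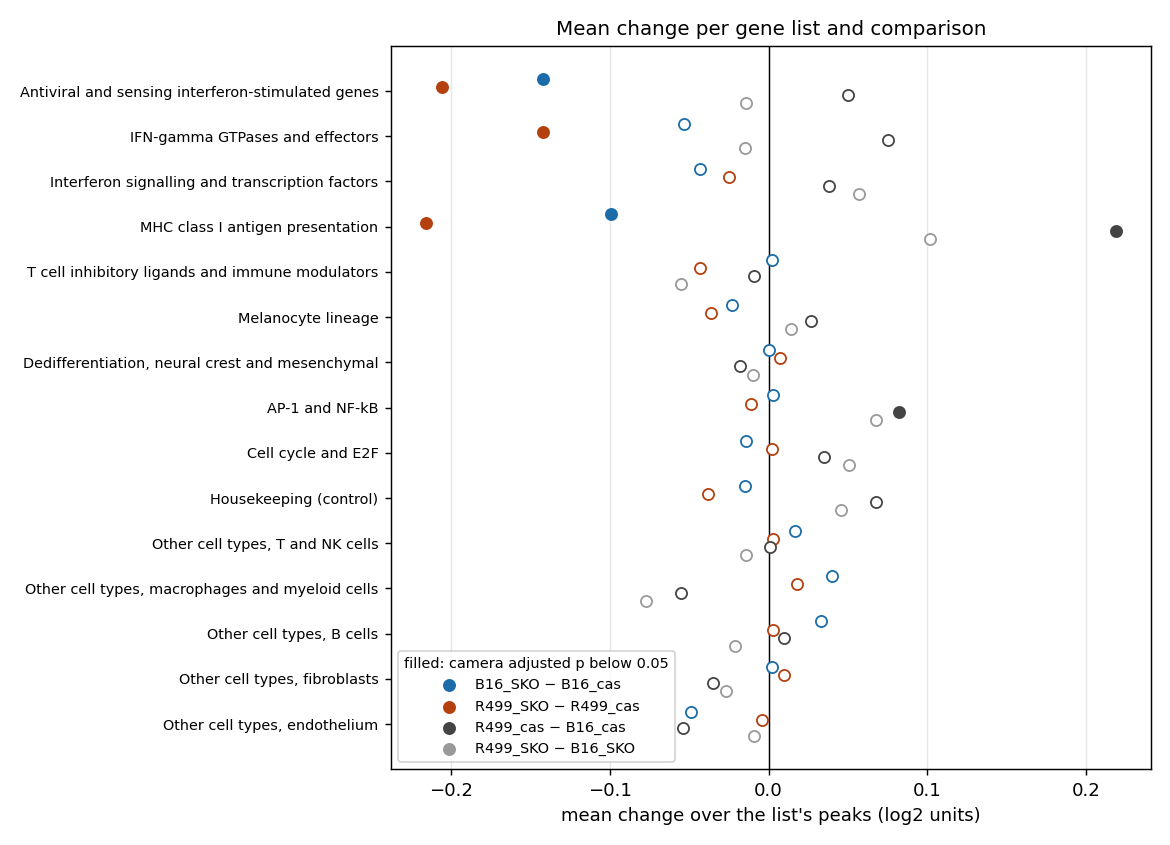
Mean log2 change (horizontal axis) of the peaks of each gene list (vertical axis) in the 4 pairwise comparisons. Filled points mark a camera adjusted p below 0.05. Antiviral genes lie at -0.142 for the knockout in B16 and -0.206 in R499, and MHC class I genes at 0.219 for R499 against B16 with STAT1.

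Whether differences between the lines depended on STAT1 was examined by following the peaks called between R499_cas and B16_cas. Of the 1310 higher peaks, 94.7% were also higher in R499_SKO than in B16_SKO, a comparison that shares no library with the call, and 832 passed there, where independent lists would share 120. Of the 1379 lower peaks, 91.4% were also lower and 681 passed, where 115 would be shared. Median changes were 0.48 with and 0.34 without STAT1 for the higher peaks, and -0.52 and -0.29 for the lower peaks. Choosing peaks on the first comparison lowers the second by itself, and simulation of a line effect without a knockout effect gave 0.54 and 0.49 for the higher peaks and -0.59 and -0.55 for the lower peaks. That simulation took the fitted changes of called peaks as true and set the line effect of all others to 0. It thus understates the lowering by selection, and its 0.54 exceeds the 0.48 found. The lower medians without STAT1 therefore do not show that the line differences depended on STAT1. The 1379 lower peaks also include 146 on chromosome 15 and 233 on chromosome 6. The medians of these chromosomes were -0.081 and -0.071 with STAT1, but -0.02 and 0.004 without it. Shifts of chromosomes may thus enter the -0.29 beside selection, and how far they do was not tested. The correlation of the line changes with and without STAT1 over all peaks was 0.52.

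In the knockout comparison of R499, which shares the R499_cas libraries with the call, the 1310 higher peaks had a median change of -0.027. Simulation of libraries with the line effect and no knockout effect gave -0.03 (from -0.043 to -0.02 in 20 simulations). For the 1379 lower peaks the median was 0.091 against a simulated 0.033 (0.019 to 0.041). Because the simulation understates selection, as above, the larger median does not by itself show an effect of the knockout. The lower peaks also include 146 on chromosome 15, whose median knockout change in R499 was 0.069 over all its peaks. That shift may enter the 0.091 too. With no effect at all the simulated medians were -0.167 and 0.166. Of these peaks 35 higher ones passed as lower in the knockout and 28 lower ones passed as higher, Nr3c2 among the latter. Over all peaks the covariance of both comparisons was -0.00825 and the simulated covariance without effects -0.00934, a difference of 0.00109. Both comparisons use the 3 libraries of R499_cas, which are too few to divide between them. Without R499_cas 2 the medians were -0.078 and 0.132, and without R499_cas 1 the higher peaks had -0.056.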

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

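The tests on gene ends and on the genotype tag in this part were chosen after the result was seen. Counts of other splits of the libraries were planned.

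Knockout changes that differed between the lines by the interaction test of limma were found at 15 named peaks. The knockout change was higher in R499 at Nr3c2 (1.72), Spef2 (1.17), both Adgrb3 peaks (1.11 and 1.03), a peak near no gene on chromosome 1 (112141255 to 112142004, 0.98), Nkain3 (0.91), a peak near no gene on chromosome 8 (116142758 to 116143507, 0.82), Tafa5 (0.8) and Slco1a6 (0.73). It was lower in R499 at Tyrp1 (-1.13), Bhlhb9 (-1.04), Alyref2 (-0.94), Rab40b (-0.84), Fam102b (-0.84) and a peak near no gene on chromosome 4 (72946404 to 72947153, -0.8). None of these genes is in an interferon list. Of 100 splits drawn of the STAT1 status within the lines, 2 gave as many calls as the 166 found, the real one included, and the highest other gave 211, so another split exceeded the real count.

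The search for single libraries far from their group covered B16_SKO and R499_SKO only, and B16_cas and R499_cas were not tested. Values of 1 library far from the others of its group were found in 15 of 160 groups tested, where chance gives about 8. B16_SKO 3 held 8 of them. Its highest value was 12.31 (others 10.96 to 11.26), its mean correlation within the group 0.976 (others 0.98 to 0.981), its melanocyte list mean 5.672 (5.744 to 5.77) and its housekeeping list mean 5.864 (6 to 6.054). At single peaks it read 5.25 for Cntn4 (4.6 to 4.7), 7.82 for the Mitf end (8.31 to 8.46), 4.84 for Phyhipl (4.26 to 4.42) and 4.84 for Nkain3 (4.54 to 4.6). Its library weight was 0.52.

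The MHC class I list mean of R499_SKO 3 was 5.682 (5.723 to 5.738) and the dedifferentiation list mean of R499_SKO 1 was 5.182 (5.19 to 5.191). Single peaks were Alyref2 in B16_SKO 1 at 7.91 (8.26 to 8.39), Stat1 in R499_SKO 1 at 7.8 (7.68 to 7.7), Gbp2 in R499_SKO 5 at 5.67 (5.44 to 5.48), Car2 in B16_SKO 4 at 4.19 (4.48 to 4.54) and A830018L16Rik in B16_SKO 2 at 4.17 (4.52 to 4.63).

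For the knockout in B16, 1 of the 56 splits of its libraries, the real one, gave 282 calls or more and the highest other gave 148. For the knockout in R499 it was 1 of 56, with 448 calls against 10. For the lines without STAT1 it was 1 of 100 drawn, with 11779 against 640. In these 3 comparisons no other split tried gave as many calls. The splits treat libraries as exchangeable, although they may be only technical replicates. They cannot tell STAT1 status or line from another difference between the groups' cells or preparation. For the lines with STAT1 the 10 splits are too few for a share under 0.05, with 2689 calls against 4.

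Gene ends made up 57.7% of the peaks higher in R499_cas and 4.1% of the lower ones. After regional centring they still made up 52.7% of the higher calls, which argues against copy number or other regional shifts as the cause. After class and level centring they made up 33.2% of the higher and 16.8% of the lower calls (two-sided Fisher's exact test p = 6.3e-15). That test counts peaks as independent, although all share the same libraries. Centring removes only a median per bin. A weaker contrast between open and closed sites in the B16 libraries that varies among the peaks of a bin would remain. As the whole or as part of the cause, such a contrast cannot be told apart from the line. Class and level centring gave 1713 calls, with 1429 of the 2689 kept, and every R499 library had a larger gene-end excess (at least 1.63) than every B16 library (at most 1.52). A true difference in accessibility of promoters between the lines stays open as well.

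The STAT1 status of 8 libraries differs between title and genotype tag. If the tag were right, grouping by it would give at least as many knockout calls in R499, but it gave 0 by limma (448 with the titles), and 5 instead of 282 in B16. This argues against the tag, and the deposited sample sheet gives the status of the titles in all 16 libraries.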

How the results depend on the processing

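Regional centring and class and level centring were chosen after the result was seen, and the other alternatives were planned. Of 5245 values of named peaks under alternatives, 387 lost a call, 14 gained one in the same direction, 31 changed sign with a call in at least 1 of both fits, and 4813 did none of these. Values that pass in neither fit count among the last even where their sign differs. Of 1720 values of lists, the numbers were 12, 34, 1 and 1673. Depth is unknown, which leaves open how much of the spread is counting error. Motif tests and their alternatives were not run. The cause of the changes below was not tested, except that fewer libraries enter where libraries are left out.

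The libraries showed no strong pairing by replicate number. The deviations of 19 pairs with the same number correlated at -0.016 to 0.058, with a mean of 0.013 against -0.003 for other pairs. Of them 0 pairs were above 0.1, and 12 of 38 best matches had the same number. The number of best matches expected by chance is not given, so a weak pairing stays open. With the number as a block, calls were 217 for the knockout in B16, 429 in R499, 2450 for the lines with STAT1, 12358 without it and 169 for the interaction.

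Calls for the knockout in B16 (282) were 184 without the variance trend, 92 with only the groups compared, 185 with library weights, 171 with a change of at least 0.5, 158 after regional centring, 5 with the genotype tag, 34 with libraries whose labels agree, and 92 to 451 with 1 library left out. For R499 (448) they were 1397 with only the groups compared, 1563 with library weights, 0 with the tag (limma, with no other tool run), 3 with agreeing labels and 156 to 641 with 1 library left out. For the lines with STAT1 (2689) they were 1742 after quantile normalization, 1315 at 0.5, 1657 after regional and 1713 after class and level centring, 9079 with the tag, 117 with agreeing labels, and 1161 to 3686. For the lines without STAT1 (11779) they were 1892 at 0.5, 2702 with the tag, 294 with agreeing labels, and 9398 to 12002. For the interaction (166) they were 106 without the trend, 349 with weights, 99 after regional centring, 1 with the tag, 0 with agreeing labels, and 66 to 324.

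Lists called by camera for the knockout in B16 (2) were 1 with an estimated correlation, agreeing labels, or class and level centring, and 1 to 2 with 1 library left out. For R499 (3) they were 5 with gene-end peaks alone. For the lines with STAT1 (2) they were 6 within 10 kb, 6 with gene-end peaks alone, 0 with an estimated correlation, 5 with agreeing labels, 1 after class and level centring, and 1 to 5. For the lines without STAT1 (0) they were 3 within 10 kb and 6 with gene-end peaks alone, and for the interaction (0) 0 to 3. With gene-end peaks alone the dedifferentiation list reversed from -0.01 to 0.103 without STAT1. Lists restricted to gene ends or to 10 kb were tested against all peaks. Calls between the lines that these restrictions add therefore do not separate a list from gene ends as a class.

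The median knockout change in R499 of peaks higher in R499_cas (-0.027) ranged from -0.078 to -0.03 with 1 R499_cas library left out, and that of the lower peaks (0.091) from 0.117 to 0.132.

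With the genotype tag these changes reversed for the knockout in R499: Nr3c2 -0.5, Ptx3 -0.44, Spef2 -0.57, Adgrb3 -0.12, Klhl29 -0.6, Lypd6 -0.27, Pdcd1 -0.39, Kit -0.15, the chromosome 1 peak (112141255 to 112142004) -0.28, Trim30a 0.84, Trim12c 0.57, Trim30d 0.32, Ifi47 0.34, Oas1h 0.64, Oas1a 0.54, Rph3a 0.39, Clec2d 0.54, the chromosome 6 peak (76546219 to 76546968) 0.62, Rtp4 0.57, Ifi203 0.27, Ifit1 0.21, Tgtp1 0.25, Irgm2 0.16, Tap1 0.22, Tap2 0.45, Psmb9 0.15, Il18bp 0.22, Met 0.18 and Ccl5 0.15. In B16 Ywhaz reversed to -0.03, and between the lines without STAT1 Oas1a reversed to 0.57.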

Other observations

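The tests in this part were chosen after the result was seen.

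A stretch of chromosome 10 from 90 Mb on was more accessible in R499 than in B16. It holds 1311 peaks, of which 367 were higher and 25 lower in R499_SKO than in B16_SKO, so that 28% of its peaks rose against 9.2% of all peaks, and 136 were higher and 10 lower in R499_cas than in B16_cas. Genes there include Cdk4, a kinase of the G1 phase of the cell cycle, Stat2, the partner of STAT1 in type I interferon signalling, and Pmel. The end of Cdk4 changed by 0.52 with STAT1 (limma adjusted p = 0.0056) and 0.58 without (2.8e-06), that of Stat2 by 0.29 (0.14) and 0.45 (1e-04), and a peak inside Pmel by 0.60 (0.0043) and 0.90 (1.3e-10). After regional centring the values were lower at all 3, with 0.39 (0.067) and 0.37 (0.0031) at Cdk4, 0.05 (0.87) and 0.17 (0.19) at Stat2, and 0.33 (0.20) and 0.63 (4.6e-06) at Pmel. Cdk4 and Pmel with STAT1 and Stat2 without it no longer passed. The stretch was not the only one with higher values in R499. On chromosome 1 from 70000001 to 100000000, windows had medians of 0.107, 0.087 and 0.117 with STAT1. Without it they had 0.104, 0.074 and 0.147. Chromosome 17 from 20000001 to 40000000 had 0.107 and 0.116 with STAT1, but 0.024 and 0.004 without. Chromosome 19 up to 10000000 had 0.126 and 0.06.

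A gain in copy number of this stretch in R499 is a candidate explanation of part of the shift. Such a gain would raise peaks of every kind, and peaks away from gene ends lay 0.105 above all such peaks with STAT1 and 0.17 above them without it. Gene ends lay 0.224 above all gene ends with STAT1. The rlog scale understates changes of weak peaks, and gene-end peaks have higher values than other peaks. The larger gene-end value therefore does not decide whether every peak shifted equally. Every R499 library lay above every B16 library (lowest 0.036, highest -0.051), with an SD within groups of at most 0.022. The stretch was chosen after the values were seen, so this separation is in part fixed by that choice. Many gene ends in the stretch do not account for the whole, since gene ends made up 16.2% of its peaks against 20.3% overall and the 0.105 is of peaks away from them. A regional change of chromatin without a change in copy number stays open, and no DNA copy number was measured here.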
